A study of Mus musculus with 2 samples.

How the data were processed

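Single-cell RNA sequencing (10x Genomics 3′ chemistry, version 3.1) measured kidney cells of male C57BL/6J mice that ate a normal-potassium or a low-potassium diet for 4 weeks. Each diet was given to 3 mice. Samples from 2 mice per diet were used, mixed and loaded as 1 library per diet with a target of 6000 cells. The cells had been sorted as living and CD45-negative, frozen and passed through a dead-cell removal step, so leukocytes were largely taken out before sequencing. A library is therefore the only unit of comparison, and a diet cannot be separated from its library.

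The deposited matrices hold counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized. Per the labels, the authors used Cell Ranger and genome build mm10, and named Seurat for later steps. No version of either tool and no annotation release was given. The matrices list 32285 genes and the barcodes that Cell Ranger called as cells. The normal-potassium library had 5608 barcodes and 63231949 UMIs, and the low-potassium library 8050 barcodes and 102592725 UMIs. No deposited cell annotation was used.

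Cells were kept with at least 200 detected genes and at most 30% mitochondrial UMIs. The gene minimum removed 37 and 3 barcodes in the normal-potassium and low-potassium libraries, and the mitochondrial maximum 348 and 330. Scrublet, run in each library, marked 0.0357% and 0% of barcodes by its automatic threshold, which is too few to be useful. By the fallback fixed in advance, the barcodes of highest score were removed at 0.8% per 1000 barcodes, or 252 (4.49%) and 518 (6.44%). This left 5032 cells (89.7%) and 7231 cells (89.8%). Both libraries were clustered together with scanpy 1.11.5: log-normalized counts, 2000 variable genes chosen within library, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0, with no batch integration. Of 25 clusters, 20 were named from marker lists written in advance and 5 stayed unnamed. A class was compared when both libraries held at least 100 of its cells, which left 5 of 8 named classes. Thick ascending limb, distal convoluted tubule and mural cells were not compared for this reason.

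UMIs were summed per library and class and scaled by the total UMIs of the class sum to CPM. Counts have exact Poisson 95% intervals, ratios exact conditional binomial intervals and shares of cells Clopper-Pearson intervals. These cover counting error only and not the spread between mice, which 1 library per diet does not show. For that reason no p-value, standard error or number of changed genes is given. A gene at 0 in 1 library was set to a floor of 3 counts per class sum and its ratio read as a bound.

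The classes, gene lists, rule for named genes and most alternatives were set before the data were examined. Named genes followed 1 rule. A leading gene needed at least 50 CPM and 30 UMIs in the library where it was higher, at least 20% of its highest CPM over the named classes there, and a ratio interval without 1. The 10 largest ratios in each direction were taken for proximal tubule and the 3 largest for each other class. Some genes that the rule names are not used here. Nlrp3, Pycard, Casp1, Gsdmd, Il1b and Il18 were read in every class, as were the leading members of each gene list. The text names members only from the 3 of largest ratio for each list outside the middle 95% of its random lists. This last choice was made after the values and the alternatives were seen.

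The 30 gene lists cover the NLRP3 inflammasome, chemokines, NF-kB targets, interferon response, antigen presentation by MHC class I and class II, tubular injury, proximal tubule segments and transport, ammoniagenesis, fatty acid oxidation, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cell cycle, matrix, endothelial activation, NRF2 targets, unfolded protein response, dissociation and immediate early genes, complement, ribosomal proteins, and water and urea transport. Another 5 lists, on salt and potassium transport along the distal nephron and on collecting duct growth, were tied to classes that were not compared and gave no value. Some names are short forms. Glycolysis stands for the glycolysis and hypoxia list, and NRF2 targets for the NRF2 and oxidative stress list. NF-kB targets stands for the list of NF-kB pathway members and targets. Their medians therefore do not describe glycolytic enzymes, NRF2 targets or NF-kB targets alone. A list was summarised in a class by the median log2 ratio of its members with at least 10 UMIs over both libraries. The median was placed among the medians of 10000 random lists of the same size and mean expression. A member counted as higher or lower at a ratio of at least 1.5 with a counting interval without 1, and as neither otherwise. The percentile describes these libraries and is not a test across mice. For shares of cells with a UMI, each cell was thinned to 1 number of UMIs, the 20th percentile of the shallower library in that class.

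Alternatives changed the mitochondrial maximum (15% and 50%), the gene minimum (1000), doublet removal, Leiden resolution (0.5 and 2.0), joint clustering, scaling, the weight of deep cells, free RNA, thinning and the UMI minimum of list members. Others, on how clusters enter a class, were added after the data had been seen. Free RNA, meaning transcripts from broken cells that enter other droplets, was estimated from the level of other classes' markers at 3.78% to 9.38% of the UMIs of a class.

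The intervals and list medians were tested on counts simulated from the class sums with 200 genes changed per class by known factors. For 200 changed genes per class, the 95% intervals covered the true ratio for 94.5% in endothelial cells, 95.5% in fibroblasts, 96.0% in podocytes, 94.5% in proximal tubule and 97.0% in thin limb. Of the 4-fold changes, the interval excluded 1 in the right direction for 99.0%, 98.0%, 96.0%, 86.0% and 93.0% in the same order. Of the 2-fold changes, it did so for 79.0%, 86.0%, 75.0%, 75.0% and 70.0%. Of 200 lists without change, 6.0%, 5.5%, 3.5%, 5.0% and 4.0% fell outside the middle 95%. The simulated counts held counting error only and the lists were random genes. These rates therefore do not cover spread between mice or lists of genes that vary together. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.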

Results

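Kidney cells from mice on a normal-potassium or a low-potassium diet were profiled by single-cell RNA sequencing, with 1 library per diet. The normal-potassium library had 63231949 UMIs over 5608 barcodes, with a median of 9032.5 UMIs and 3091 genes per barcode. The low-potassium library had 102592725 UMIs over 8050 barcodes, with medians of 7901.5 UMIs and 2839.5 genes. Median mitochondrial content was 1.75% and 2.71%. All values below compare 1 library with 1 library, and each interval covers counting error only. Where a pair of values is given, the normal-potassium library comes first.

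The first comparison asks which cells were captured under each diet. Endothelial-like cells were the largest class in both libraries, at 53.9% of kept cells (95% interval 52.5 to 55.2) under normal potassium and 30.8% (29.7 to 31.8) under low potassium. Fibroblast-like cells made up 23.7% and 16.6%, podocyte-like cells 4.53% and 3.06%, and thin limb-like cells 3.99% and 2.56%. Proximal tubule-like cells were 6.02 times as frequent in the low-potassium library, at 2.94% (2.49 to 3.45) and 17.7% (16.8 to 18.6). Cells of the thick ascending limb (0.219% and 2.88%), distal convoluted tubule (0.298% and 1.94%) and mural class (1.49% and 5.24%) were also more frequent in the low-potassium library. With the libraries clustered apart, the direction turned for thin limb (0.954% and 2.57%) and for mural cells (1.05% and 0%). The 4 tubular classes together held 7.45% and 25.1% of cells. Sorting, freezing and dead-cell removal can set such shares. The endothelial share depends on cluster 0, a cluster of low UMI count that carries endothelial markers (Pecam1, Cdh5, Emcn, Flt1, Eng and Tie1) but was left unnamed, and with it the class held 54.1% and 46.4%. Without the proximal tubule cluster of low UMI count, that class held 2.62% and 10.6%. Of the unnamed clusters, cluster 0 held 0.258% and 15.6% of cells, cluster 18 3.50% and 0.0138%, cluster 13 4.43% and 2.32%, cluster 22 0.537% and 1.01%, and cluster 24 0.278% and 0.235%.

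**Figure D1:**
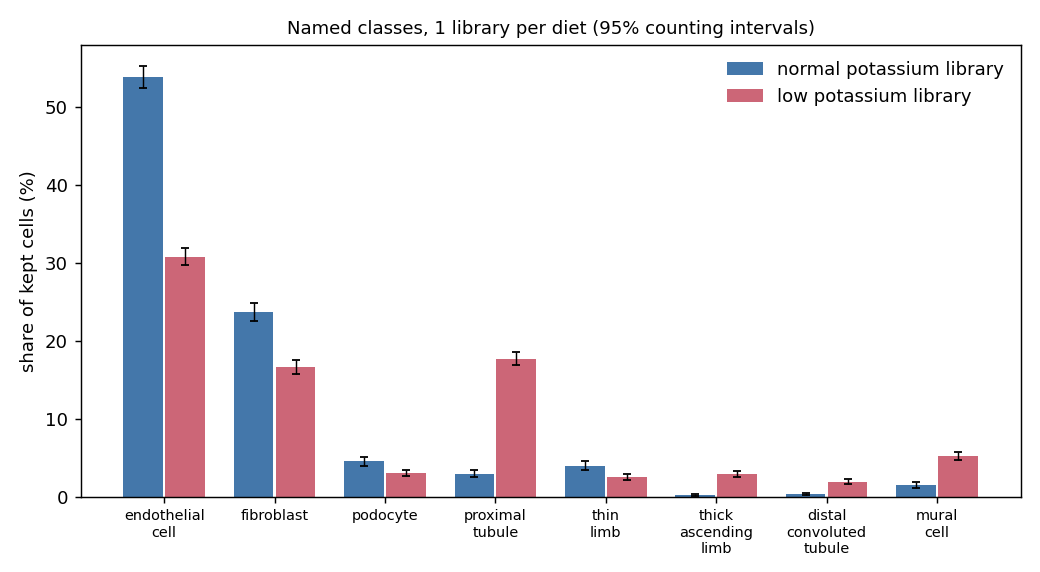
Share of kept cells (percent) in each named class, with bars for the normal-potassium and low-potassium libraries and Clopper-Pearson 95% intervals. Endothelial cells fill 53.9% and 30.8% of the libraries, and proximal tubule cells 2.94% and 17.7%.

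The study's title places NLRP3 and its adaptor ASC in kidney epithelium under low potassium, so the second comparison follows the genes of that pathway. Pycard (ENSMUSG00000030793), which encodes ASC, was higher in the low-potassium library in all 5 classes compared. The difference was wider in the epithelial classes than in fibroblasts. In proximal tubule, Pycard stood at 9.98 CPM (6.46 to 14.7) and 32.5 CPM (30.4 to 34.7), a ratio of 3.26 with a counting interval of 2.19 to 5.06. With each cell weighing the same, Pycard there had a log2 ratio of 2.88, against 1.70. In podocytes it stood at 11.5 and 36.2 CPM, a ratio of 3.16 (1.92 to 5.35), and in thin limb at 16.8 and 34.8 CPM, a ratio of 2.07 (1.5 to 2.88). Endothelial cells had 37.5 and 58.0 CPM, a ratio of 1.55 (1.41 to 1.70), which ended when the endothelial clusters were given equal weight (log2 ratio -0.0054 against 0.63). Fibroblasts had 26.2 and 32.2 CPM, a ratio of 1.23 (1.09 to 1.39).

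Cells with a Pycard UMI followed the same order after thinning to 1 depth per class. Of proximal tubule cells at 4227 UMIs, 2.54% (0.527 to 7.25) and 14.2% (11.8 to 16.8) had one, from 118 and 776 cells. The shares were 2.94% and 8.47% in podocytes, 5.23% and 10.8% in thin limb, 13.2% and 21.6% in endothelial cells and 16.7% and 19.2% in fibroblasts. Unthinned, the proximal tubule shares were 9.46% and 35.5%, and the fibroblast shares turned to 34.8% and 29.8%. No class is known to lack Pycard, so the lowest share in each library, 2.54% and 8.47%, bounds the background from free RNA. Under normal potassium that bound is the proximal tubule share itself, and the podocyte share lay close to it. The bound therefore cannot tell whether either stands above background. Depths also differed between classes, from 3864 UMIs per cell in podocytes to 7131 in fibroblasts. Under low potassium the bound is the podocyte share, and the thin limb share lay close to it, so the same limit holds for these classes.

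The sensor and the effectors of the inflammasome were not seen to share this pattern across the 5 classes. For several of them the counts were too low to tell. Nlrp3 had at most 3 UMIs in any compared class of either library, with 0 and 1 UMIs in proximal tubule, so no difference between diets can be read for it. Il1b had 0 and 4 UMIs in proximal tubule, too few to tell, and 2 and 13 in endothelial cells, the same direction as Pycard. Casp1 had at most 2 UMIs per library in proximal tubule, podocytes and thin limb, against 102 and 72 in endothelial cells and 87 and 32 in fibroblasts. Gsdmd was lower in the low-potassium endothelial cells, at 24.6 and 18.9 CPM, and did not differ beyond counting error in fibroblasts, at 20.2 and 18.6 CPM. Il18 was lower in fibroblasts, at 672 and 66 UMIs, and stood at 16.7 and 18.1 CPM in podocytes. In the direction of Pycard, Il18 had 1.60 and 3.29 CPM in proximal tubule (4 and 89 UMIs, a ratio of 2.06 with an interval of 0.776 to 7.72) and was found in 0 of 118 and 12 of 776 cells after thinning, where 0 of 118 allows up to 2.54% of cells with a UMI at this depth by the limit of 3 counts, and 3.08% by the exact interval. Gsdmd had 23.4 and 30.9 CPM in podocytes (a ratio of 1.32, 0.863 to 2.01). The inflammasome list as a whole had a median log2 ratio of 0.41 in proximal tubule, -0.15 in thin limb, -0.26 in podocytes and -0.045 in fibroblasts, each inside the middle 95% of its random lists. In endothelial cells its median of -0.27 lay below that range, although 4 of 14 members were at least 1.5 times higher, 2 lower and 8 neither, with Nek7 at 214 and 131 CPM, Casp4 higher at 78.6 and 128 CPM, and Aim2 at 17 and 31 UMIs. That median was 0.015 at Leiden resolution 0.5.

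**Figure D2:**
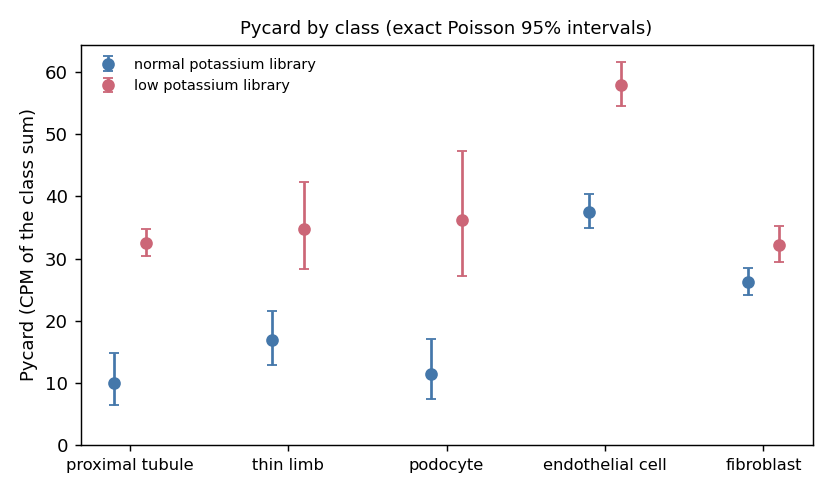
Pycard in CPM of the class sum for 5 classes, as points for each library with exact Poisson 95% intervals. The low-potassium points lie above the normal-potassium points, from 32.5 against 9.98 CPM in proximal tubule to 32.2 against 26.2 CPM in fibroblasts.

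The third comparison, within proximal tubule, addresses how the kidney's main reabsorbing epithelium differed between diets. The low-potassium class sum held less mRNA for genes of the first proximal segment (S1), among them transporters of glucose, lactate and amino acids. Such a sum does not tell a lower level per cell from a different mix of captured segments, which was not tested. The median ratios of the fatty acid oxidation list and the NRF2 list were higher, and that of the unfolded protein response lower. Single genes with the largest ratios included the glutathione transferase Gsta1 and the glutamine transporter Slc38a3. Different clusters held the class in each library: cluster 21 held 128 of 148 normal-potassium cells, and clusters 6 and 10 held 767 and 514 of 1281 low-potassium cells. The joint clustering also put 33 normal-potassium cells into thin limb that fell with proximal tubule when each library was clustered on its own. These 33 cells had a median of 43710 UMIs and would make up 36.8% of the class's normal-potassium UMIs, so list medians that turn with them are given with both assignments. The same move takes along 2 low-potassium cells, with a median of 80150 UMIs, which make up 0.588% of the low-potassium UMIs of proximal tubule with them and 5.47% of those of thin limb. Every value given with or without the 33 cells includes the move of these 2.

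Among the genes higher in the low-potassium proximal tubule, Gsta1 (ENSMUSG00000074183), a glutathione transferase, had 0.798 and 658 CPM, a ratio of 824 with an interval of 228 to 6802 because only 2 UMIs were counted under normal potassium. Slc38a3 (ENSMUSG00000010064), the glutamine transporter that feeds ammonia production, had 1.20 and 408 CPM, a ratio of 340 (117 to 1651). Cyp4a14, a fatty acid hydroxylase, had 3.99 and 497 CPM, a ratio of 125 (67.7 to 260). The quinone and carbonyl reductases Nqo1 (ratio 108, 29.9 to 893) and Cbr3 (ratio 85.3, 33.3 to 313) and the fibrinogen chain Fgg (ratio 51.4, 17.5 to 249) were higher as well. With every cell thinned to 1 depth, each of these 6 genes had only 1 or 2 normal-potassium UMIs, and the lowest bound of their ratio intervals was 5.31, for Fgg. With the 33 cells included, the ratio of Fgg was 80.7 (27.6 to 392), from 3 normal-potassium UMIs. Shisa4, Krt20, Oasl1 and Ucp2 also led by size, at log2 ratios of 6.02, 5.78, 5.72 and 5.50, but stood at 1.32, 2.33, 3.16 and 0.65 with those cells included.

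Among the genes lower in the low-potassium cells, Slc22a28 (ENSMUSG00000063590), an organic anion transporter, had 285 and 0.406 CPM, 701 times lower in the low-potassium library. The phosphate transporter Slc34a3 had 84.2 and 0.517 CPM and the long noncoding RNA Snhg11 528 and 3.88 CPM. Clec2h, Dgkb, Evc, Grid1, Slc22a30 and Cdkl1 were between 40.1 and 116 times lower. With the 33 cells included, the log2 ratios of these genes ran from -8.83 for Slc22a28 to -4.73 for Slc22a30, against -9.45 and -5.37 without them. With every cell weighing the same, Cdkl1 stood at -2.82 and Dgkb at -4.97. Malat1 held 14.2% and 9.75% of the UMIs of the class. Whether that difference bears on the lower genes was not tested.

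The gene lists gave these differences a wider frame. All 8 measured genes of the S1 segment were at least 1.5 times lower in the low-potassium class sum, with a median log2 ratio of -2.45, below each of the 10000 random lists. The lactate transporter Slc5a12 had 1215 and 110 CPM, the glucose transporter Slc5a2 758 and 83.5 CPM, and the amino acid transporter Slc7a7 400 and 58.4 CPM. Transport and endocytosis genes had a median of -0.83, with 11 of 18 at least 1.5 times lower, although the glucose transporter Slc5a1 was higher at 5.19 and 37.1 CPM (log2 ratio 2.84, and 3.53 with the 33 cells). The S2 and S3 segment lists, at -0.27 (0.11 with the 33 cells) and -0.23, lay inside the random range, as did ammoniagenesis and gluconeogenesis at 0.028, so the higher Slc38a3 was not shared by that list, where 6 of 14 genes were at least 1.5 times higher and 6 lower.

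The fuel and redox lists had higher medians. Fatty acid oxidation had a median of 1.35, above every random list, with 11 of 20 members at least 1.5 times higher and 3 lower, Cyp4a14 among the first and Acsm2, at 2498 and 142 CPM, among the others. Oxidative phosphorylation genes encoded in the nucleus had a median of 1.24 (21 of 22 higher). The glycolysis and hypoxia list had 1.30 (15 of 19 higher and 1 lower), while the mitochondrially encoded genes stood at 0.011. Pkm had 7.98 and 271 CPM, Egln3 3.99 and 105 CPM and Pdk1 2.00 and 37.9 CPM. The NRF2 and oxidative stress list had a median of 1.04 (11 of 16 higher), with Mt1 at 98.6 and 454 CPM and Srxn1 at 13.2 and 58.3 CPM beside Nqo1. The unfolded protein response was lower, at -0.61, with Hsp90b1 at 532 and 146 CPM and Hspa5 at 1228 and 417 CPM. Of its 14 genes, 6 were at least 1.5 times lower, 2 higher and 6 neither. Its largest ratio was the opposite one of Asns, at 1 and 57 UMIs, a ratio of 5.27 whose interval of 0.909 to 212 includes 1 (log2 ratio 2.40, and -1.71 with the 33 cells). With the 33 cells included, the medians were 0.92 for fatty acid oxidation, 0.59 for oxidative phosphorylation, 0.62 for glycolysis, 0.77 for NRF2 targets, -0.91 for the unfolded protein response and -1.85 for S1. The log2 ratios were then 3.02 for Pkm (5.09 without the cells), 2.00 for Egln3 (4.71), 2.52 for Pdk1 (4.25) and 0.051 for Srxn1 (2.15). Mt1 moved from 2.20 to 0.95 when each cell weighed the same.

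Injury and inflammation lists depended on where those 33 cells were placed. The tubular injury list had a median log2 ratio of 1.32 as clustered together and -0.23 with the cells included. Chemokines, cytokines and adhesion stood at 0.84 and -0.61, NF-kB targets at 0.75 and -0.43, and ribosomal proteins at 1.65 and -0.03. Clu turned from 4.17 to -0.34, Tnfrsf12a from 2.28 to -0.40 and Rela from 1.36 to -0.21. Spp1 stayed higher (290 and 1738 CPM as clustered together), at a log2 ratio of 2.58 and 1.16, as did Tnfrsf1a at 1.91 and 1.26. Lcn2 had 0 and 365 UMIs, at least 11.3-fold higher, yet at 1.22% of its level in the highest class it lay near free RNA. Interferon response (0.15), MHC class I (0.38) and class II (0.23), cell cycle (0.52), matrix (-0.061), dissociation and immediate early genes (0.60) and complement (-0.18) lay inside the random range as clustered together. With the 33 cells included, interferon response stood at -0.18, MHC class I at -0.45, class II at -0.89 and dissociation and immediate early genes at -0.18. Each cell weighing the same moved matrix to 1.09 and interferon response to 0.99. No direction for injury or inflammation in proximal tubule can be read from these libraries.

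**Figure D3:**
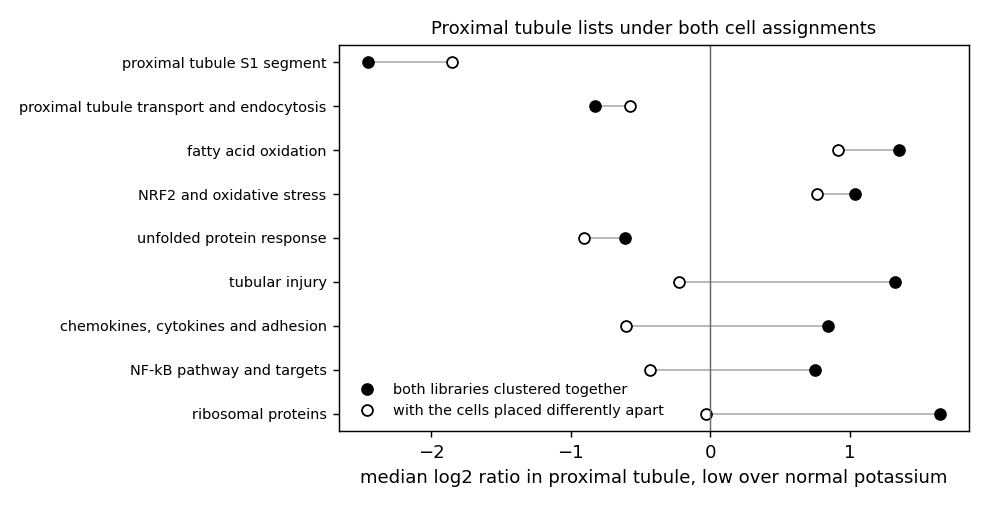
Median log2 ratio (low over normal potassium) of 9 gene lists in proximal tubule, with filled points for both libraries clustered together and open points with the 33 normal-potassium and 2 low-potassium cells that were placed differently included. S1 stays at -2.45 and -1.85, while tubular injury moves from 1.32 to -0.23.

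The fourth comparison concerns the endothelium, where circulating leukocytes attach. The low-potassium class sum held more Lrg1 and Selp mRNA. As in proximal tubule, such a sum does not tell a higher level per cell from a different mix of captured cells. The MHC class I list had a lower median, with 5 of 13 members at least 1.5 times lower and 8 neither. The NRF2 and glycolysis lists had higher medians, with 7 of 16 and 6 of 19 members at least 1.5 times higher and 9 and 13 neither. The chemokine, cytokine and adhesion list had a higher median, with 10 of 21 members up and 4 down, which turned when the clusters were weighted equally. Most cells came from different clusters, with clusters 1 and 4 holding 1039 and 860 of 2710 normal-potassium cells and clusters 2 and 5 holding 983 and 525 of 2225 low-potassium cells.

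Lrg1 (ENSMUSG00000037095) had 3.15 and 139 CPM, a ratio of 44.2 (34.4 to 57.7). P-selectin (Selp) had 29.2 and 328 CPM, a ratio of 11.2 (10.3 to 12.2), and E-selectin (Sele) 62.8 and 203 CPM. Mctp1 had 7.30 and 75.5 CPM, but its log2 ratio of 3.37 was 0.85 with the clusters weighted equally. Il6 had 6.55 and 45.7 CPM, Cxcl10 34.6 and 194 CPM and endothelin (Edn1) 53.5 and 149 CPM. The natriuretic peptide receptor Npr3 was lower at 771 and 133 CPM, as were Brip1 at 118 and 21.4 CPM and Ctnna3 at 234 and 48.5 CPM. MHC class I genes had a median log2 ratio of -0.55, below each random list, with Psmb9 at 102 and 49.1 CPM, Tap2 at 124 and 71.8 CPM and H2-T23 at 395 and 230 CPM. MHC class II stood at -1.03 (6 of 7 members lower), with H2-Ab1 at 60.7 and 29.4 CPM, H2-Eb1 at 21.0 and 8.66 CPM and H2-DMb1 at 10.6 and 4.13 CPM.

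NRF2 targets had a median of 0.68, above each random list, with Nqo1 at 4.50 and 16.2 CPM and Srxn1 at 7.55 and 16.3 CPM. With that weighting the log2 ratios were also smaller for Selp (2.06), Cxcl10 (0.73), Sele (0.34), Npr3 (-1.26) and Ctnna3 (-1.09), H2-Ab1 (0.15) and H2-Eb1 (0.44) turned, Il6 was lowest at 1.20 with doublets kept, and Lrg1 and Edn1 at 4.24 and 0.69 in the clusters both libraries share. The glycolysis and hypoxia list stood at 0.33, led by Slc2a1 at 22.3 and 73.9 CPM, Ndrg1 at 145 and 305 CPM and Pdk1 at 21.2 and 40.4 CPM. The chemokine list had a median of 0.58 and endothelial activation 0.27 (7 of 18 higher and 4 lower), both outside the random range. With the clusters weighted equally, these were -0.089 and -0.065, and MHC class II was 0.15. NF-kB targets had a median of 0.25, with 6 of 20 members higher and 1 lower: Bcl3 had 32.3 and 70.3 CPM and Tnfrsf12a 31.9 and 72.6 CPM, against C3 at 50.5 and 13.2 CPM. The medians of ribosomal proteins (0.34), oxidative phosphorylation (0.28) and mitochondrially encoded genes (0.44) lay above the random range, though only 3 of 18, 1 of 22 and 3 of 13 members were at least 1.5 times higher. That of the unfolded protein response lay below it at -0.22, with 5 of 14 members lower and 2 higher, Hsp90b1 at 495 and 270 CPM among the first. The mitochondrially encoded median was -0.057 when each cell weighed the same. Interferon response (-0.069), cell cycle (0.14), matrix (0.11), dissociation and immediate early genes (-0.072) and complement (-0.096) lay inside the random range. Endothelial Spp1, at 10.1 and 162 CPM, was 1.52% of its highest class and turned to a log2 ratio of at most -2.11 once free RNA was subtracted, which left no low-potassium UMI.

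In fibroblasts the low-potassium library had lower medians for the interferon response, MHC class I and unfolded protein response lists. The clusters of the class differed in weight between libraries, as cluster 8 held 441 of 1191 normal-potassium and 135 of 1203 low-potassium cells. Interferon response had a median of -0.52 (10 of 22 members lower), with Ifit1 at 140 and 38.6 CPM, Gbp2 at 120 and 56.1 CPM and Rtp4 at 28.9 and 14.5 CPM. That median was -0.14 with the clusters weighted equally. MHC class I stood at -0.51, with 3 of 13 members at least 1.5 times lower, among them H2-K1 at 658 and 343 CPM and Psmb9 at 33.8 and 15.2 CPM. The unfolded protein response stood at -0.45 (6 of 14 lower), with Hspa5 at 1990 and 1049 CPM and Sdf2l1 at 49.5 and 16.0 CPM. The oestrogen sulfotransferase Sult1e1 was 43.3 times lower at 80.8 and 1.87 CPM, Adamts16 had 60.2 and 3.22 CPM and Nptx2 59.5 and 4.89 CPM. The clock gene Nr1d1 (7.98 and 90.0 CPM) and the apolipoprotein Apod (35.0 and 376 CPM) were higher. Mitochondrially encoded genes stood at 0.29, outside the random range, with 1 of 13 higher. Chemokines (0.0019), NF-kB targets (-0.025), MHC class II (-0.30), matrix and fibrosis (0.12), NRF2 targets (0.083), glycolysis (0.11), oxidative phosphorylation (0.098), cell cycle (0.24), dissociation and immediate early genes (0.11), complement (0.25) and ribosomal proteins (-0.047) lay inside it. Of 19 matrix genes, 7 were at least 1.5 times higher and 7 lower. With the clusters weighted equally, the log2 ratios moved to -3.70 for Sult1e1, -2.28 for Adamts16, -1.45 for Nptx2, -0.64 for Ifit1, -1.35 for Il18 and -0.27 for Casp1, and Apod stood at 2.57 with doublets kept.

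Podocytes had a higher median for the list of dissociation and immediate early genes and a lower one for the unfolded protein response. The first list, which tissue handling also raises, had a median of 0.81, above each random list, with 11 of 18 members higher and 3 lower, Junb at 663 and 2009 CPM and Ier2 at 305 and 886 CPM among the first and Hspb1 at 856 and 240 CPM among the others. The median of the unfolded protein response stood at -0.72, below each random list (7 of 12 lower and 2 higher), with Hspa5 at 1040 and 544 CPM and Sdf2l1 at 37.2 and 8.05 CPM, against Atf4 at 157 and 311 CPM. The glucocorticoid-responsive gene Fkbp5 had 5.73 and 67.1 CPM, a ratio of 11.7 (6.42 to 23.4), Zc3h6 11.5 and 76.5 CPM and Egr2 11.9 and 73.8 CPM. The prostaglandin synthase Ptgds was 33.5 times lower at 158 and 4.70 CPM, Sorcs1 had 95.5 and 3.35 CPM and Frmd5 53.5 and 8.05 CPM. NRF2 targets stood at 0.38 (5 of 15 higher) and ribosomal proteins at 0.29 (0 of 18 at least 1.5 times higher), outside the random range. Chemokines (0.38), NF-kB targets (0.21), interferon response (-0.0078), MHC class I (0.14), oxidative phosphorylation (0.18), mitochondrially encoded genes (0.12), glycolysis (0.13), cell cycle (-0.25), matrix (-0.14) and complement (0.29) lay inside it. Only 2 MHC class II genes were measured, which gave no median. The log2 ratio of Ptgds moved from -5.07 to -2.25 with doublets kept, that of Fkbp5 from 3.55 to 2.73 with every cell thinned, and that of Frmd5 from -2.73 to -2.08 at the wider mitochondrial maximum. That of Sorcs1 came closer to 0 with each cell weighing the same.

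In thin limb the low-potassium cells had a strong interferon signature, opposite to fibroblasts. Of 22 interferon genes, 19 were at least 1.5 times higher, with a median log2 ratio of 1.59 that stayed at 1.40 without the 33 cells. Leaving out these cells checks only part of the class. With the libraries clustered apart, 0.954% of normal-potassium cells were named thin limb, against 3.99% together. Most of the 201 normal-potassium thin limb cells thus lost that name, and no thin limb ratio could be taken under that setting. Ifit1 had 9.07 and 189 CPM, a ratio of 20.9 (14.7 to 30.4), Isg15 4.54 and 79.5 CPM and Ifi27l2a 3.74 and 56.7 CPM. MHC class I stood at 0.65 (8 of 13 members higher), with Psmb8 at 11.7 and 33.1 CPM, Tap1 at 8.27 and 19.8 CPM and Nlrc5 at 13.3 and 24.9 CPM. The log2 ratios of Tap1 (1.26), Nlrc5 (0.90), Isg15 (4.13) and Ifi27l2a (3.92) were as low as 0.32, 0.31, 3.12 and 2.38 under an alternative, and that of Psmb8 0.22. The cystine transporter Slc7a11 had 1.07 and 59.4 CPM, a ratio of 55.7 (21.4 to 207), and NRF2 targets a median of 0.54 (7 of 16 higher and 2 lower). The median of NF-kB targets stood at 0.32, although 3 of 20 members were higher and 3 lower, with Tnfrsf1a at 34.7 and 68.3 CPM, against C3 at 380 and 70.7 CPM and Tnip1 at 52.8 and 28.0 CPM, whose log2 ratio turned from -0.92 to 0.093 without the 33 cells. Water and urea transport genes stood at -0.71 (7 of 12 lower and 1 higher), with Aqp2 at 53.9 and 1.37 CPM, Avpr2 at 10.7 and 1.37 CPM, and Aqp4 at 65 and 0 UMIs, at least 16.9-fold lower. These 3 genes are known from collecting duct principal cells, and a difference in such cells within the class cannot be told from one in thin limb cells. The median of the unfolded protein response was -0.43, with 6 of 14 members lower and 2 higher, among them Herpud1 at 209 and 114 CPM and Asns at 13.3 and 29.7 CPM. Other medians lay outside the random range although almost no member differed by 1.5 times. Dissociation and immediate early genes stood at -0.25, with 1 of 18 lower, 1 higher and 16 neither, Fos at 2833 and 2027 CPM and Ier3 at 227 and 402 CPM. Ribosomal proteins stood at 0.30, with 0 of 18 at least 1.5 times higher.

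Several other thin limb values changed without the 33 cells. Ugt2b37 had 180 and 1.37 CPM, Sfrp5 55.2 and 0.341 CPM, and Wfdc16 321 and 0 UMIs. Without those cells Ugt2b37 had 3 and 3 UMIs, so its difference was lost, and Sfrp5 and Wfdc16 had at most 1 UMI per library. MHC class II turned from -1.19 to 0.68, oxidative phosphorylation from -0.18 to 0.34, Gpx3 from -2.13 to 2.55 and Gpx1 from -1.72 to 0.65. Complement stood at -0.84 and -0.0099 without them, with C3 at -2.43 and -0.49, while Cd55 (-2.23 and -2.21) and the MHC class II member H2-DMb1 (-1.16 and -1.19) kept their log2 ratios. The complement median also turned to 0.44 with members of at least 50 UMIs, and was -2.56 with free RNA subtracted. Chemokines (-0.14, and 0.68 without the 33 cells), mitochondrially encoded genes (0.15), glycolysis (-0.11), cell cycle (0.11) and matrix (-0.13, and 0.27 without the 33 cells) lay inside the random range as clustered together.

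Across classes, the unfolded protein response was the list that stood below its random range in all 5 classes, with medians from -0.72 in podocytes to -0.22 in endothelial cells. The endothelial median lay near the edge of that range, at percentile 2.33 against a bound of 2.5. The NRF2 and oxidative stress list stood above its random range in proximal tubule, thin limb, podocytes and endothelial cells, and inside it in fibroblasts. The interferon response median was higher in thin limb and lower in fibroblasts, and that of MHC class I higher in thin limb and lower in fibroblasts and endothelial cells.

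**Figure D4:**
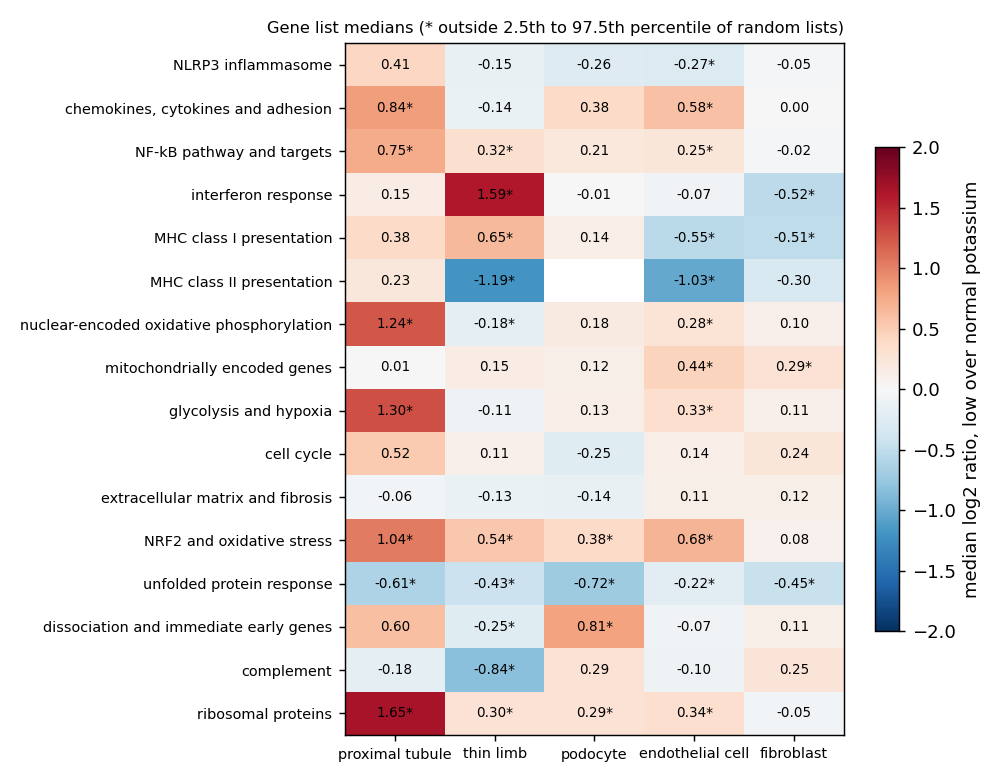
Median log2 ratio (low over normal potassium) of 16 gene lists in 5 classes as clustered together, with an asterisk outside the middle 95% of random lists. The unfolded protein response runs from -0.72 to -0.22, while interferon response runs from 1.59 in thin limb to -0.52 in fibroblasts.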

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

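Of the tests in this part, the depth of endothelial cells, the comparison within a range of Malat1 share and the thinning of proximal tubule cells were chosen before the result each measures was seen, and the other 6 after it.

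Some gene lists lay on opposite sides between classes of the same libraries, and these differences between classes were not tested. Interferon response had a median log2 ratio of 1.59 in thin limb and -0.52 in fibroblasts. MHC class I stood at 0.65 in thin limb, -0.55 in endothelial cells and -0.51 in fibroblasts. The list of dissociation and immediate early genes stood at 0.81 in podocytes and -0.25 in thin limb. Oxidative phosphorylation stood at 0.28 in endothelial cells and 1.24 in proximal tubule but at -0.18 in thin limb, where moving the 33 normal-potassium and 2 low-potassium cells turns it to 0.34.

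Signals also stood above the limit that a count of 0 allows in cells the comparisons did not use. In the low-potassium library, Lcn2 had 1102 CPM in thick ascending limb, 239 CPM in distal convoluted tubule and 440 CPM in cluster 22, which carries markers of connecting tubule and intercalated cells. The normal-potassium library had 0 Lcn2 UMIs in its 11 thick ascending limb and 15 distal convoluted tubule cells, and 2.68 CPM in 27 cells of cluster 22. Pycard had 55.6 and 125 CPM in distal convoluted tubule and 64.3 and 129 CPM in cluster 22, with the normal-potassium library first.

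The first pattern weighed is a lower median of genes with male-biased expression in the low-potassium proximal tubule. The 12-gene list had a median log2 ratio of -1.20, with 9 members lower and 3 higher, the highest at 2.12. It was written after 9 of its values had been seen, so only the other 3 can test lower androgen-dependent expression. Their median of -0.22 decides nothing, and the diet, the mice and the library cannot be told apart. A list of 6 genes with female-biased expression, 4 of them measured, had a median of 1.39, with 3 higher and 1 lower. That median lay inside the random range, at percentile 97.28. The list includes the leading gene Cyp4a14, and its measured genes had only 1 to 22 normal-potassium UMIs, so it decides nothing either. Loss of S3 cells is left open. The median over all 8 S3 genes was -0.23, but 4 of the 8 are taken as sex-biased, so this test partly restates the pattern. The other 4, used in a first version of the test, had a median of 1.5, with 3 higher and 1 lower, which goes against such a loss but leaves out leading genes. Whether only the captured cells differ is open too: as free RNA in endothelial cells, the log2 median of 5 of these genes differed by -0.88 from other proximal tubule markers, but only 2 of the 5 are clearly lower in proximal tubule itself, so this value decides nothing, and Kap, the gene first tried, had a log2 ratio of -4.73 in endothelial cells.

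The second pattern is that endothelial cells part by library. Depth as the whole cause is argued against, since cross-library neighbours of thinned cells reached only 0.199 of the number expected by chance. A different makeup of capillary types stays open. Over 243 genes, the difference between clusters 2 and 4 correlated at 0.71 with that inside the shared cluster 5, but free RNA alone would give 0.64, so the correlation decides nothing. The differences inside cluster 5 had a median absolute log2 ratio of 0.87, against 0.036 expected from free RNA alone. The expected value holds no counting error, which by itself raises an observed absolute ratio, so they cannot be compared directly. Whether cluster 5 mixes capillary types was not tested. A batch effect on the whole library is left open. Fibroblasts had 1.65 times the cross-library neighbours of endothelial cells, between the bounds set for and against it. Over the number expected by chance, these neighbours reached 0.175 in endothelial cells, 0.290 in fibroblasts, 0.483 in podocytes, 0.597 in thin limb and 0.0584 in proximal tubule, so the classes parted to unequal degrees, and their cell numbers were not matched. No test here separates such a batch effect from the diet.

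The third pattern is the higher ribosomal and respiratory chain mRNA in the low-potassium proximal tubule. Loss of cytoplasmic RNA from normal-potassium cells, as the whole cause, is argued against by a ribosomal median log2 ratio of 1.43. It came from cells with 5% to 15% of UMIs on Malat1 (76 and 973 cells). The match was loose, since these cells still had 11.15% and 9.16% of UMIs on Malat1, against 14.2% and 9.75% in the whole class. A part played by such loss stays open. Thinning gave 1.66 but cannot test depth, since it keeps proportions within a cell. A candidate explanation is the placement of 33 normal-potassium cells in thin limb, since counting them, and 2 low-potassium cells placed the same way, as proximal tubule gave a ribosomal median of -0.03 and a respiratory chain median of 0.59. Whether those cells are proximal tubule in another state was not tested independently.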

How the results depend on the processing

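All alternatives on how clusters enter a class (cluster 0 as endothelial, cluster 13 as fibroblast, equal cluster weights, shared clusters, cluster 15 alone, without cluster 10 and the move of 33 normal-potassium and 2 low-potassium cells) were chosen after the data had been seen, and the others before. No paired analysis was possible because each diet has 1 library of mixed samples. The unfolded protein response stayed below 0 in all 5 classes, and NRF2 targets above 0 in proximal tubule, thin limb, podocytes and endothelial cells, under every alternative run. Among the weakest of these were -0.13 in endothelial cells and -0.15 in proximal tubule for the unfolded protein response, and 0.031 in thin limb and 0.097 in podocytes for NRF2 targets. Random lists were not drawn anew under the alternatives. These values therefore show the side of 0 only, not whether a median stayed outside its random range. Pycard stayed above 0 in every class and alternative except for endothelial cells with clusters weighted equally. Of 88 list medians, 45 stayed on their side of 0 under every alternative, and of 179 log2 ratios of named genes, 158. Values moved beyond their counting interval, or for a list beyond the interval of its median, in 39 of 116 shares of cells. Of 1306 list median values under the alternatives, 69 moved and 19 turned. A list median counted as turned only if its reported value lay outside the random range, and a gene ratio only if its interval excluded 1. Other medians that crossed 0 counted as moved, or as unchanged inside that interval. Unchanged ones, such as dissociation and immediate early genes in proximal tubule (0.60, and -0.18 with the 33 cells), are not listed below. For named genes other than Pycard, 575 of 2421 values moved and 24 turned. Some of the moved values are only bounds, because a library had 0 UMIs under that alternative, as for Il18 in proximal tubule with every cell thinned.

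The genes above are those the text can name, a subset set after the alternatives had been seen. Over all 389 genes that the wider rule names, 52 turned under at least 1 alternative, in 91 of 5358 values, and 37 of these 52 are outside the subset. Thin limb could not be compared with the libraries clustered apart, since too few normal-potassium cells were left. Sfrp5 and Wfdc16 have no thin limb value once those cells are moved, and MHC class II in podocytes has none under any setting. Weighing each cell the same shifted the median of all proximal tubule genes from 0.091 to 0.30, and free RNA subtraction to -0.11. Depth limits podocytes, with 2094803 and 1490538 UMIs, and the normal-potassium proximal tubule, with 2505112 UMIs against 27089505.

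Shares of cells, list medians and Pycard values that turned or moved, and other gene ratios that turned, follow by alternative, with the reported value in brackets. Other gene ratios that moved are given only as the count above, 368 of them nearer to 0 and 207 farther from it. Medians and ratios are log2, and the cause was not tested unless stated.

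At Leiden resolution 0.5, shares of cells were 35.1% (53.9%) in the normal-potassium library and 25.4% (30.8%) in the low-potassium library in endothelial cells, 31.6% (23.7%) in the normal-potassium library and 18.9% (16.6%) in the low-potassium library in fibroblasts. List medians were 0.015 (-0.27) for inflammasome and 0.13 (0.34) for ribosomal proteins in endothelial cells. At Leiden resolution 2.0, shares of cells were 43.0% (53.9%) in the normal-potassium library and 34.6% (30.8%) in the low-potassium library in endothelial cells, 21.7% (23.7%) in the normal-potassium library in fibroblasts, 2.79% (5.24%) in the low-potassium library in mural cells. Proximal tubule had 11.2% (17.7%) in the low-potassium library, 3.34% (3.99%) in the normal-potassium library in thin limb. List medians were 0.61 (0.44) for mitochondrially encoded genes and 0.20 (0.34) for ribosomal proteins in endothelial cells, 0.024 (-1.19) for MHC class II, 0.32 (-0.18) for oxidative phosphorylation, -0.68 (-0.13) for matrix, -0.42 (-0.25) for dissociation and immediate early genes and 0.55 (0.30) for ribosomal proteins in thin limb. Log2 ratios were 0.059 (-1.79) for H2-Ab1, 0.27 (-0.72) for Cycs, 0.28 (-0.39) for Atp5g1, 0.57 (-0.29) for Ndufv1, 0.57 (-2.13) for Gpx3 and 0.45 (-1.72) for Gpx1 in thin limb.

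With at least 1000 detected genes, shares of cells were 2.29% (1.94%) in the low-potassium library in distal convoluted tubule, 45.0% (53.9%) in the normal-potassium library and 29.3% (30.8%) in the low-potassium library in endothelial cells, 28.2% (23.7%) in the normal-potassium library and 17.5% (16.6%) in the low-potassium library in fibroblasts. Proximal tubule had 14.5% (17.7%) in the low-potassium library, 3.52% (2.88%) in the low-potassium library in thick ascending limb. List medians were 0.22 (0.34) for ribosomal proteins in endothelial cells, -0.051 (0.083) for NRF2 targets and -0.16 (-0.047) for ribosomal proteins in fibroblasts, -2.93 (-1.19) for MHC class II in thin limb. With cluster 0 counted as endothelial, shares of cells were 46.4% (30.8%) in the low-potassium library in endothelial cells. List medians were 0.71 (0.44) for mitochondrially encoded genes, -0.15 (-0.072) for dissociation and immediate early genes and 0.18 (0.34) for ribosomal proteins in endothelial cells. With clusters weighted equally, list medians were -0.089 (0.58) for chemokines, 0.15 (-1.03) for MHC class II, -0.065 (0.27) for activation, -0.29 (-0.072) for dissociation and immediate early genes and 0.056 (0.34) for ribosomal proteins in endothelial cells, 0.20 (-0.025) for NF-kB targets, -0.14 (-0.52) for interferon response, 0.44 (0.083) for NRF2 targets, -0.17 (0.11) for dissociation and immediate early genes and 0.27 (-0.047) for ribosomal proteins in fibroblasts, 0.034 (-0.18) for oxidative phosphorylation, 0.71 (0.15) for mitochondrially encoded genes, -0.38 (-0.25) for dissociation and immediate early genes and 0.21 (0.30) for ribosomal proteins in thin limb. Log2 ratios were -0.0054 (0.63) for Pycard, 0.44 (-1.28) for H2-Eb1 and 0.15 (-1.04) for H2-Ab1 in endothelial cells.

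With doublets kept, shares of cells were 49.5% (53.9%) in the normal-potassium library and 26.5% (30.8%) in the low-potassium library in endothelial cells, 28.2% (23.7%) in the normal-potassium library and 18.8% (16.6%) in the low-potassium library in fibroblasts, 11.7% (17.7%) in the low-potassium library in proximal tubule. List medians were 0.26 (0.12) for mitochondrially encoded genes in podocytes, -2.83 (-1.19) for MHC class II and 0.77 (-0.13) for matrix in thin limb. With every cell thinned, log2 ratios were 0.85 (0.63) for Pycard in endothelial cells. With free RNA subtracted, list medians were 0.28 (0.44) for mitochondrially encoded genes, 1.23 (-0.096) for complement and 0.40 (0.34) for ribosomal proteins in endothelial cells, -0.055 (0.098) for oxidative phosphorylation and -0.0074 (0.083) for NRF2 targets in fibroblasts, 1.95 (1.65) for ribosomal proteins in proximal tubule. Thin limb had 0.91 (0.65) for MHC class I and -2.56 (-0.84) for complement. Log2 ratios were -2.11 (4.00) for Spp1 in endothelial cells. With the libraries clustered apart, shares of cells were 0% (0.298%) in the normal-potassium library in distal convoluted tubule, 45.6% (53.9%) in the normal-potassium library in endothelial cells, 22.04% (16.6%) in the low-potassium library in fibroblasts. Mural cells had 1.05% (1.49%) in the normal-potassium library and 0% (5.24%) in the low-potassium library, 0% (0.219%) in the normal-potassium library in thick ascending limb, 0.954% (3.99%) in the normal-potassium library in thin limb. List medians were 0.62 (0.44) for mitochondrially encoded genes in endothelial cells, -0.099 (-0.047) for ribosomal proteins in fibroblasts, -0.60 (0.84) for chemokines, -0.43 (0.75) for NF-kB targets, -0.43 (0.38) for MHC class I, -0.89 (0.23) for MHC class II, -0.25 (1.32) for tubular injury, 0.58 (1.24) for oxidative phosphorylation, 0.61 (1.30) for glycolysis and -0.031 (1.65) for ribosomal proteins in proximal tubule. Log2 ratios were -0.40 (2.28) for Tnfrsf12a, -0.22 (1.36) for Rela and -0.34 (4.17) for Clu in proximal tubule.

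With each cell weighing the same, list medians were 0.44 (0.28) for oxidative phosphorylation, -0.057 (0.44) for mitochondrially encoded genes and 0.46 (0.34) for ribosomal proteins in endothelial cells, 1.21 (0.41) for inflammasome, 1.44 (0.84) for chemokines, 0.99 (0.15) for interferon response, -0.43 (0.011) for mitochondrially encoded genes, 1.09 (-0.061) for matrix and 1.43 (1.65) for ribosomal proteins in proximal tubule, -0.014 (-0.18) for oxidative phosphorylation and 0.19 (0.30) for ribosomal proteins in thin limb. Log2 ratios were 0.91 (0.63) for Pycard in endothelial cells, 2.88 (1.70) for Pycard in proximal tubule, 0.20 (-0.29) for Ndufv1 in thin limb. With median-of-ratios size factors, list medians were 0.020 (0.083) for NRF2 targets and -0.11 (-0.047) for ribosomal proteins in fibroblasts. With list members of at least 50 UMIs, list medians were 0.44 (-0.84) for complement in thin limb. At a mitochondrial maximum of 15%, shares of cells were 32.0% (30.8%) in the low-potassium library in endothelial cells, 14.7% (16.6%) in the low-potassium library in fibroblasts, 2.31% (2.94%) in the normal-potassium library and 16.3% (17.7%) in the low-potassium library in proximal tubule. Thick ascending limb had 0.0408% (0.219%) in the normal-potassium library. List medians were -0.057 (0.083) for NRF2 targets and -0.15 (-0.047) for ribosomal proteins in fibroblasts, 0.78 (0.23) for MHC class II in proximal tubule.

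At a mitochondrial maximum of 50%, shares of cells were 14.5% (16.6%) in the low-potassium library in fibroblasts, 3.84% (2.94%) in the normal-potassium library in proximal tubule, 4.62% (3.99%) in the normal-potassium library in thin limb. List medians were 0.0054 (0.083) for NRF2 targets and -0.13 (-0.047) for ribosomal proteins in fibroblasts, 0.21 (0.12) for mitochondrially encoded genes in podocytes. With cluster 15 alone as thin limb, list medians were -0.33 (-0.18) for oxidative phosphorylation and 0.21 (0.30) for ribosomal proteins in thin limb. In the endothelial clusters both libraries share, list medians were -0.35 (-0.072) for dissociation and immediate early genes in endothelial cells. Log2 ratios were 0.41 (0.63) for Pycard in endothelial cells. With the 33 normal-potassium and 2 low-potassium cells moved from thin limb to proximal tubule, list medians were -0.61 (0.84) for chemokines, -0.43 (0.75) for NF-kB targets, -0.18 (0.15) for interferon response, -0.45 (0.38) for MHC class I, -0.89 (0.23) for MHC class II, -0.23 (1.32) for tubular injury, 0.59 (1.24) for oxidative phosphorylation, 0.62 (1.30) for glycolysis and -0.030 (1.65) for ribosomal proteins in proximal tubule, 0.55 (0.32) for NF-kB targets, 0.68 (-1.19) for MHC class II, 0.34 (-0.18) for oxidative phosphorylation, -0.41 (-0.25) for dissociation and immediate early genes and 0.55 (0.30) for ribosomal proteins in thin limb. Log2 ratios were -0.40 (2.28) for Tnfrsf12a, -0.21 (1.36) for Rela and -0.34 (4.17) for Clu in proximal tubule, 0.093 (-0.92) for Tnip1, 0.99 (-1.79) for H2-Ab1, 1.17 (-1.20) for Cd74, 0.28 (-0.72) for Cycs, 0.34 (-0.39) for Atp5g1, 0.57 (-0.29) for Ndufv1, 2.55 (-2.13) for Gpx3 and 0.65 (-1.72) for Gpx1 in thin limb.

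Thinned to the median depth, shares of cells with a Pycard UMI were 22.3% (13.2%) in the normal-potassium library and 27.7% (21.6%) in the low-potassium library in endothelial cells, 27.7% (16.7%) in the normal-potassium library and 31.9% (19.2%) in the low-potassium library in fibroblasts, 18.9% (8.47%) in the low-potassium library in podocytes. Proximal tubule had 14.9% (2.54%) in the normal-potassium library and 35.4% (14.2%) in the low-potassium library, 18.7% (5.23%) in the normal-potassium library and 32.3% (10.8%) in the low-potassium library in thin limb. Unthinned, shares of cells with a Pycard UMI were 18.5% (13.2%) in the normal-potassium library and 29.8% (21.6%) in the low-potassium library in endothelial cells, 34.8% (16.7%) in the normal-potassium library and 29.8% (19.2%) in the low-potassium library in fibroblasts, 8.33% (2.94%) in the normal-potassium library and 15.8% (8.47%) in the low-potassium library in podocytes. Proximal tubule had 9.46% (2.54%) in the normal-potassium library and 35.5% (14.2%) in the low-potassium library, 18.4% (5.23%) in the normal-potassium library and 30.3% (10.8%) in the low-potassium library in thin limb.

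Without the proximal tubule cluster of low UMI count, shares of cells were 10.6% (17.7%) in the low-potassium library in proximal tubule.

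For proximal tubule, the move of the 33 and 2 cells and the libraries clustered apart share their cause by construction, since both count these cells as proximal tubule. The shares without cluster 10 and of cells with a Pycard UMI move by construction too, through the cells left out and the UMIs per cell. The cause was not tested for the others.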

Other observations

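The cells and genes in this part were chosen after their values were seen, and no test was run on them.

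Cells of the distal nephron, which takes part in potassium handling, were too few to be compared. In distal convoluted tubule (15 and 140 cells, with 8.72% and 5.67% of UMIs mitochondrial), the normal-potassium cells were 0% of the library with the libraries clustered apart. As clustered together, the sodium chloride cotransporter Slc12a3 had 9700 and 3668 CPM, parvalbumin (Pvalb) 581 and 25.3 CPM and Egf 1211 and 339 CPM. In thick ascending limb (11 and 208 cells, with 16.6% and 6.24% of UMIs mitochondrial), the normal-potassium cells were 0.0408% of the library at a mitochondrial maximum of 15% and none with the libraries clustered apart. There Egf had 4743 and 352 CPM, Slc12a1 7831 and 2551 CPM, and Umod 9172 and 6415 CPM. Spp1 had 956 and 10680 CPM in these cells and 606 and 5014 CPM in distal convoluted tubule, and Gdf15 42.8 and 209 CPM in thick ascending limb. Pycard had 42.8 CPM (15.7 to 93.1) and 84.7 CPM (78.3 to 91.4) in thick ascending limb, from 6 and 651 UMIs, a ratio whose counting interval of 0.90 to 5.41 includes 1. Nlrp3 had 0 and 1 UMIs in thick ascending limb and none in distal convoluted tubule.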
